A study of Rattus norvegicus with 13 samples.

How the data were processed

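Total RNA from the hypothalamus of male Sprague-Dawley rats was measured on 13 Affymetrix expression arrays. Biotinylated cRNA had been prepared from 100 ng of total RNA with the GeneChip WT PLUS protocol. According to the labels, rats arrived at 6 to 7 weeks of age, were assigned at random to 1 of 3 diets, ate freely for 2 months and were 14 to 15 weeks old at tissue collection. The hypothalamus was micro-dissected with the anterior commissure and the mammillary bodies as landmarks. The low-fat control diet (16% of energy as soybean oil) had 4 arrays, the high-fat flaxseed oil diet (35% of energy) had 4 and the high-fat safflower oil diet (35% of energy) had 5. The labels do not say whether each array held RNA of a single rat, and each array was treated as an independent sample. No batch, hybridisation date or RNA quality value was given in the sources used here.

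The deposited table holds 1 log2 signal per array for each of 70580 transcript clusters, and the authors made these log2 values with RMA (background correction, quantile normalization of probes and median polish). The submitters' processing notes name Affymetrix Expression Console, RMA and Transcriptome Analysis Console without versions. The genome build behind the transcript clusters is not given in the sources used here, so no position is printed. Values ran from 1.99 to 14.46 on the log2 scale over the 13 arrays. The number of arrays limits the precision: the median standard error of a log2 change was 0.0817 for flaxseed against low-fat and 0.0775 for both comparisons with the safflower group, giving median 95% confidence half-widths of 0.174 and 0.165.

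Of the transcript clusters, 1738 were control features. Among the others, 23446 were annotated with exactly 1 gene symbol, 505 with several and 44891 with none. Only those with exactly 1 symbol were used as genes. The gene IDs of 22077 were matched to the RefSeq annotation of assembly GRCr8, which changed 1 symbol. Where a gene had several transcript clusters (1182 genes), the one with the highest mean over the 13 arrays was taken, leaving 22093 genes. Genes with a mean at or above the median of all transcript cluster means (6.58) were tested, 16033 in all.

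The comparisons, tests, gene lists, naming rule and most alternatives were fixed before the data were examined. Group means for the 3 diets were fitted in a single model with limma 3.58.1 in R 4.3.3 (lmFit and eBayes with the default prior, 10 residual degrees of freedom). The contrasts were flaxseed minus low-fat, safflower minus low-fat, safflower minus flaxseed, and the mean of both high-fat diets minus low-fat, with a moderated F test of any difference among the 3 diets. P-values were adjusted by the Benjamini-Hochberg method over the genes tested, with a threshold of 0.05. All tests were two-sided. The deposited values were not normalized again. The plan kept them as they were if the columns shared a distribution, and the columns did so only in part, with medians from 6.42 to 6.74. Alternative scalings are therefore given beside the affected results.

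A total of 30 gene lists (pathways, cell types, brain regions and neighbouring tissues) with 836 symbols were fixed, of which 780 matched a gene on the array and 740 were tested. Lists were tested with limma's camera at a preset correlation between genes of 0.01, adjusted over the lists within a comparison. The same test with an estimated correlation, fry, and an exact permutation of array labels on list means were also run, and list medians were set among 10000 random lists of the same size matched on mean signal. Random lists lack the correlation between genes of a real list, so the percentiles describe a list and do not test it. With 4 against 5 arrays the smallest two-sided permutation p is 0.00794, and with 4 against 4 it is 0.0286. The relation between both high-fat effects, which share the low-fat arrays, was set beside 100 simulations of unchanged groups and 6 splits of the low-fat arrays.

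Named genes followed a rule: the 10 genes with the highest and the 10 with the lowest log2 change among those past the threshold, filled with the smallest unadjusted p where fewer passed, and the 2 members with the smallest unadjusted p of each list that passed the list test and of the lists on feeding peptides, fatty acid desaturation, fatty acid oxidation, eicosanoids and inflammation. For cell type, region, ribosomal and blood lists the rule gives the count and the median only. Provisional symbols, like-gene symbols and olfactory, vomeronasal and taste receptors were excluded from naming but counted in the totals, while trace amine-associated receptors such as Taar6 were not excluded. The exclusion was extended after the values were seen to further olfactory receptor names, pseudogenes and further forms of like-gene symbols. A symbol ending in l and a number counted as a like-gene only where the part before it is itself a gene symbol. This match was corrected after the values were seen, as it had left out Myl2 and Myl11.

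The alternatives fixed beforehand were quantile normalization and median centring of the columns, the mean filter at the 25th and 75th percentiles and none, all transcript clusters that were not controls, the mean of a gene's transcript clusters, array weights, a trended robust prior, an ordinary fit without moderation, a fit of only the groups compared, replicate number as a block, an unadjusted p under 0.05 with a fold of at least 1.5, and each array left out in turn. Chosen after seeing the data were cyclic loess, quantile normalization over the genes tested only, quantile normalization with each array left out, the median of 1128 olfactory receptor transcript clusters as a covariate, and the permutation of list means. Whether arrays with the same replicate number belonged together was checked on 12 pairs. After removal of the group means 7 correlated above 0.1, and 4 of 12 arrays resembled their own number best. The r was 0.18 to 0.43 for replicates 1 and 4 and -0.33 to 0.30 for replicates 2 and 3. The numbers were therefore not used to pair arrays, but a factor shared by number was not excluded. The procedure was tested on simulated data with the residual spread of these arrays, independent noise for each gene and 50 changed genes per size among 16033. For flaxseed against low-fat it recovered 20% of genes with a log2 change of 0.25, 88% at 0.5 and 96% at 1. For safflower against low-fat it recovered 28%, 86% and 100%, and for safflower against flaxseed 26%, 78% and 100%. Genes on the real arrays vary together, so these rates need not hold for them. Figures were drawn with matplotlib 3.10.9 in Python 3.11.15. Raw probe intensities were not used here.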

Results

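The arrays measured hypothalamic transcripts of male rats fed for 2 months a low-fat soybean oil diet (n = 4), a high-fat diet with flaxseed oil, rich in the omega-3 alpha-linolenic acid (n = 4), or a high-fat diet with safflower oil, rich in the omega-6 linoleic acid (n = 5). Signals are RMA values on the log2 scale, and 16033 genes were tested with limma. The series asks what a high intake of either essential fat does to hypothalamic gene expression, so each high-fat diet was compared with the low-fat diet and the high-fat diets with each other.

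The first principal component carried 37.0% of the variance and ran from the low-fat arrays (-19.06 to -10.91) through the flaxseed arrays (-8.10 to 4.76) to the safflower arrays (0.70 to 22.46). The spread of signals differed between diets. The interquartile range of the tested genes was 1.36 ± 0.03 (SD, n = 4) on the low-fat, 1.46 ± 0.05 (SD, n = 4) on the flaxseed and 1.58 ± 0.06 (SD, n = 5) on the safflower arrays, with an exact permutation p = 0.00794 for safflower against low-fat (the smallest p that 4 against 5 arrays allow; adjusted p = 0.0357) and 0.0571 for flaxseed against low-fat (adjusted p = 0.0857). Signals of olfactory receptor genes, which served as a measure of background, had a median of 5.03 ± 0.08 (SD, n = 4), 4.87 ± 0.05 (SD, n = 4) and 4.75 ± 0.04 (SD, n = 5) in the same order, and their median log2 change with safflower was -0.267. The median of the negative control features was 5.59 ± 0.22 (SD, n = 4), 5.58 ± 0.21 (SD, n = 4) and 5.41 ± 0.28 (SD, n = 5), with an exact permutation p = 0.333 for safflower against low-fat (adjusted p = 0.391). The median of the positive control features was 8.99 ± 0.08 (SD, n = 4), 9.21 ± 0.06 (SD, n = 4) and 9.29 ± 0.09 (SD, n = 5), with an exact permutation p = 0.00794 for safflower against low-fat (adjusted p = 0.0357). Spike-in features had a median of 6.14 ± 0.19 (SD, n = 4), 6.02 ± 0.12 (SD, n = 4) and 5.85 ± 0.04 (SD, n = 5). For safflower against low-fat their exact permutation p was 0.0238 (adjusted p = 0.0593). Log2 changes against low-fat ran with signal level. With the genes ordered by mean signal into 10 groups of equal size, the safflower median was -0.211 in the dimmest group and 0.259 in the brightest, against -0.0151 and 0.0287 after quantile normalization.

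**Figure D1:**
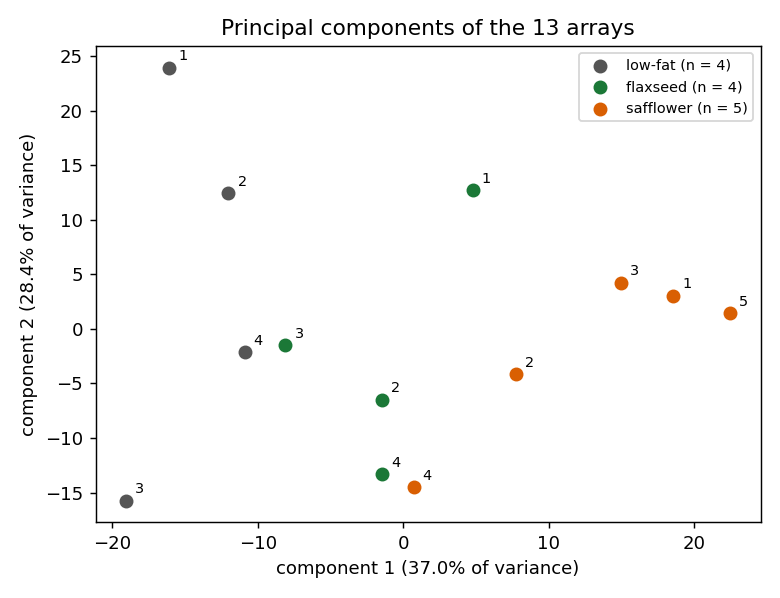
Each point is 1 array, placed by its scores on the first (x axis) and second (y axis) principal components of the tested genes, with percent of variance on the axes, colour for diet and the replicate number beside it. Low-fat arrays lie at -10.91 or below on the first component and safflower arrays at 0.70 or above.

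**Figure D2:**
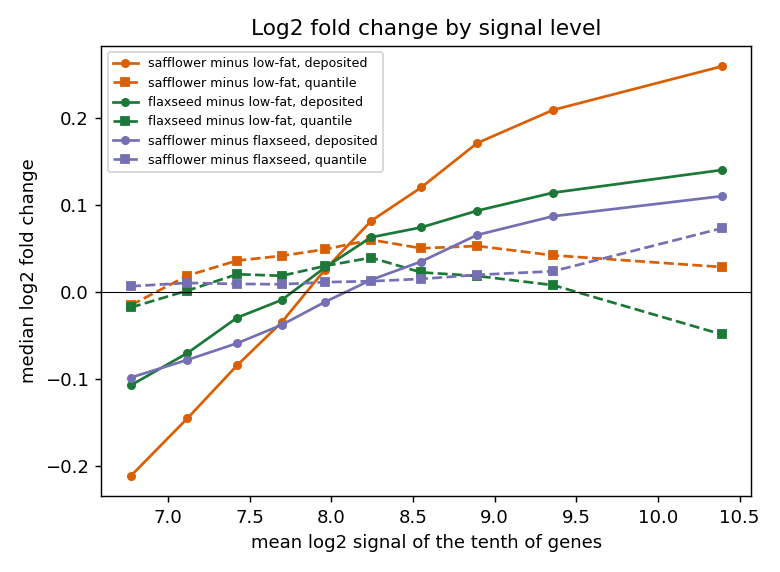
Median log2 fold change (y axis) of 10 equal groups of the tested genes, ordered by mean log2 signal (x axis), for the 3 comparisons with the deposited scaling (solid lines) and after quantile normalization (dashed lines). With the deposited scaling the safflower against low-fat medians run from -0.211 to 0.259.

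Compared with the low-fat diet, the gene lists of glutamate and GABA transmission and of cholesterol synthesis were higher with the safflower diet (camera adjusted p = 1.39e-05 and 0.00809). Neither passed with an estimated correlation (adjusted p = 0.892 for both) or after quantile normalization (camera adjusted p = 0.496 and 0.327). Hadhb, the beta subunit of the mitochondrial trifunctional protein that oxidises long-chain fatty acids, rose 1.37-fold, from 8.60 ± 0.07 (SD, n = 4) to 9.05 ± 0.14 (SD, n = 5; log2 change 0.45, SE 0.07, limma adjusted p = 0.00379). Msmo1, a sterol oxidase of cholesterol synthesis, rose 1.35-fold, from 9.54 ± 0.05 (SD, n = 4) to 9.98 ± 0.15 (SD, n = 5; log2 change 0.43, SE 0.07, limma adjusted p = 0.00379). Gria3, a subunit of AMPA-type glutamate receptors, rose 1.38-fold, from 9.23 ± 0.08 (SD, n = 4) to 9.69 ± 0.18 (SD, n = 5; log2 change 0.47, SE 0.08, limma adjusted p = 0.00379). Hnrnph2, an RNA-binding protein, had the highest log2 change of the named genes (0.70, SE 0.09, 1.62-fold, limma adjusted p = 0.00371). All 5 safflower arrays lay above all low-fat arrays for these 4 genes. Such a separation, in either direction, was found for 3921 of the 6377 genes past the threshold, so it does not single these 4 out.

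In all, 6377 genes passed the threshold in this comparison, 3675 higher and 2702 lower with safflower (57.6% higher), with a median fold of 1.22 for the higher and 1.21 for the lower genes. At an unadjusted p under 0.05 the count was 8184, where 801.65 would be expected by chance. Fold sizes reached 1.5 in 31 of the higher and 20 of the lower genes. The count and its direction followed the scaling. Quantile normalization left 2326 genes (69.9% higher; 880 and 1275 without low-fat replicates 1 and 2, and 1031, 1299 and 949 without safflower replicates 1, 3 and 5), cyclic loess 3332 (45.7% higher), and median centring, which moved the median log2 change of all genes from 0.07 to 0.28, gave 9620 (98.3% higher). The same direction past the threshold with deposited, quantile and loess scaling was found for 1540 genes, 931 higher and 609 lower. With the olfactory receptor median of each array as a covariate limma gave 0 (793 at an unadjusted p under 0.05).

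Of the 38 genes named for this comparison, 12 passed in the same direction with deposited, quantile and loess scaling: besides the 4 above, Ano3 (log2 change 0.62), Etfdh (0.26), Lta4h (0.40), Ptger1 (-0.31), Tnni2 (-0.69), Taar6 (-0.64), C16h10orf71 (-0.64) and Tcap (-0.61). Etfdh carries electrons from fatty acid oxidation to the respiratory chain, Lta4h makes leukotriene B4 and Ptger1 is a receptor of prostaglandin E2. None of the 12 passed with the olfactory covariate, which correlated at -0.94 with the grouping and raised the standard error 2.39-fold in the median. The log2 changes were then larger in size for Tnni2 (-0.93), C16h10orf71 (-0.93) and Tcap (-0.75), 0.51 for Ano3, from 0.21 to 0.32 for Hadhb, Hnrnph2, Lta4h, Gria3 and Msmo1, -0.06 for Ptger1 and turned for Etfdh (-0.03) and Taar6 (0.16). Ptger1 did not pass after median centring (adjusted p = 0.207). For 11 of the 12 the call also held without each single array. Ano3 did not pass without any 1 of the 4 low-fat arrays or without safflower replicate 1 or 5, where its adjusted p was 0.0664 to 0.0936. The named genes on the lower side included genes of skeletal muscle. Myl11 (log2 change -1.04, SE 0.36), Tnnt3 (-0.91), Ckm (-0.81), Myh4 (-0.76), Tnni2 and Tcap fell with safflower. Low-fat replicate 3 stood at 9.29 for Myl11 against 6.86 to 7.19 in the other low-fat arrays and at 9.62 for Tnnt3 against 7.30 to 7.65. Myl11 did not pass with quantile (-0.89, adjusted p = 0.153) or loess scaling (-0.86, adjusted p = 0.135) or after median centring (adjusted p = 0.0557). Without low-fat replicate 3 the log2 changes were -0.46 for Myl11, -0.36 for Tnnt3, -0.37 for Ckm, -0.32 for Myh4, -0.52 for Tnni2 and -0.48 for Tcap, all still past the threshold, while Car3 (-0.81 with all arrays) did not pass without it (-0.51, adjusted p = 0.094). Myl11, Tnnt3, Ckm, Myh4 and Car3 each failed to pass without some other single array, at adjusted p up to 0.0632, 0.0833, 0.0681, 0.0683 and 0.071.

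**Figure D3:**
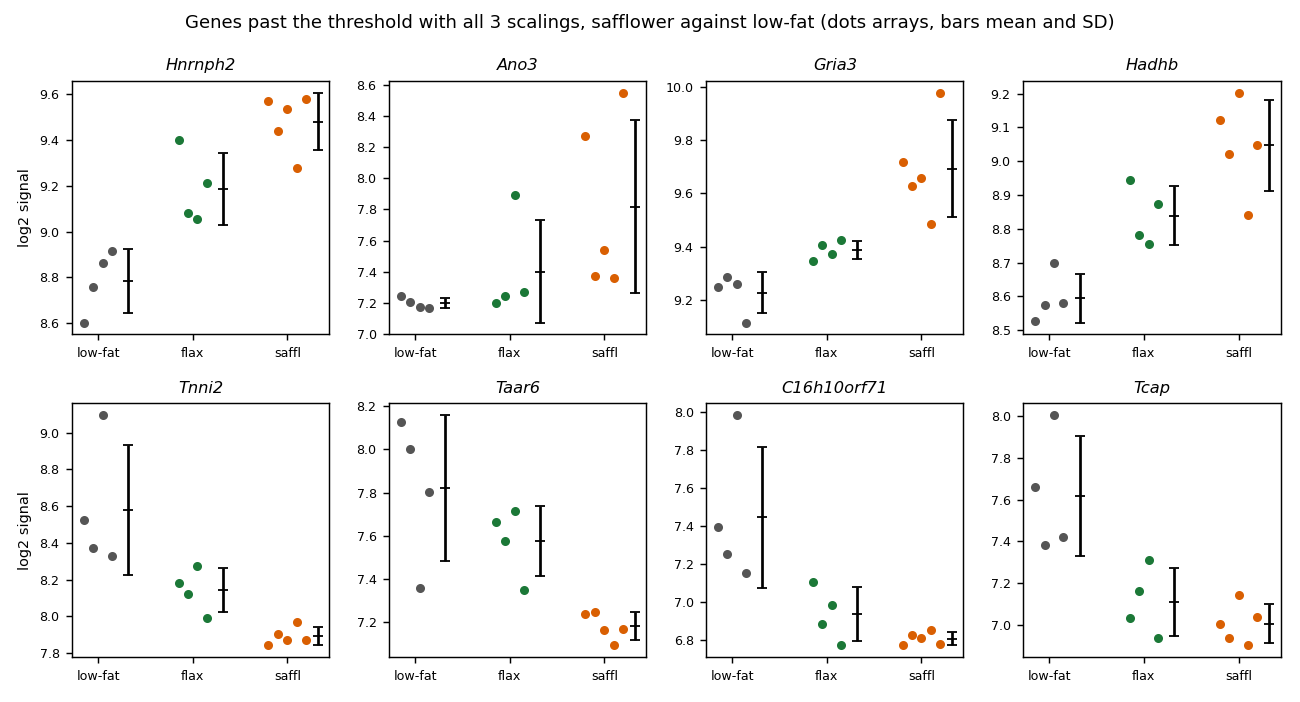
Log2 signal (y axis) of 8 named genes that passed the threshold for safflower against low-fat with deposited, quantile and loess scaling; dots are arrays by diet, and bars give the mean and SD. The 4 genes in the upper panels were higher and the 4 in the lower panels lower with safflower, and low-fat replicate 3 is the highest low-fat array for Tnni2, C16h10orf71 and Tcap.

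In the list of transmission by glutamate and GABA, 22 of 29 members were higher with safflower and none lower (24 when adjusted over the list alone; camera adjusted p = 1.39e-05, median log2 change 0.35). Neither this list nor any of the other 11 that passed for safflower against low-fat did so with an estimated correlation (adjusted p = 0.892 for each) or after quantile or loess normalization. Syp, a synaptic vesicle protein, rose by 0.44 on the log2 scale, and Gabrb2, a GABA-A receptor subunit, by 0.62. With quantile normalization 1 member of this list passed, and in the cholesterol list 4 were higher, in fatty acid desaturation 2, in the respiratory chain 3 with 1 lower, in ribosomal proteins 1 with 2 lower and among astrocyte markers none. Cholesterol synthesis had 11 of 22 members higher (13 adjusted over the list alone; adjusted p = 0.00809), with Msmo1 and Sc5d (0.33) the members of smallest p. Fatty acid desaturation, elongation and transport had 9 of 25 higher (8 adjusted over the list alone; adjusted p = 0.00809), among them Acsl4 (0.41) and Acsl3 (0.34), which activate long-chain fatty acids. The nuclear-encoded respiratory chain had 27 of 64 higher (28 adjusted over the list alone; adjusted p = 0.000143), including Ndufs4 (0.28) and Uqcrc2 (0.32). Syp, Gabrb2, Sc5d, Acsl3, Ndufs4 and Uqcrc2 did not pass with quantile normalization. Cytosolic ribosomal proteins (13 of 70 higher, 1 adjusted over the list alone; adjusted p = 0.00897) and astrocyte markers (5 of 17 higher, 5 adjusted over the list alone; adjusted p = 0.0204) were higher with the deposited scaling, but both lists pointed downward in the test with quantile and with loess scaling. Set among 10000 random lists matched on mean signal, the medians of the glutamate and GABA and the cholesterol lists lay at percentiles 100 and 99.6, those of fatty acid desaturation and the respiratory chain at 69.4 and 29.3, and those of ribosomal proteins and astrocyte markers at 0.01 and 0.45.

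Lists lower with safflower were markers of tanycytes, pituitary, hypothalamic regions and blood and genes of inflammation and interferon response (adjusted p = 0.892 for each with an estimated correlation). Among random lists matched on mean signal, the medians of the blood, pituitary, tanycyte and region lists lay at percentiles 0, 0.27, 0.39 and 2.04, and those of interferon response and inflammatory signalling at 15.3 and 44.1. Tanycyte, ependymal and choroid plexus markers had 9 of 24 members lower (9 adjusted over the list alone; adjusted p = 0.000803, median log2 change -0.20). Pituitary markers had 5 of 8 lower and 1 higher (6 and 1 adjusted over the list alone; adjusted p = 0.00809), and hypothalamic region markers 5 of 29 lower and 1 higher (4 and 1 adjusted over the list alone; adjusted p = 0.0169). Inflammatory signalling had 10 of 25 lower and 1 higher (10 and 1 adjusted over the list alone; adjusted p = 0.0174), with Il1b (-0.34) and Ccl5 (-0.33) as examples. With quantile normalization none of the inflammatory members was lower and 1 was higher (list median -0.003), and neither Il1b (log2 change -0.15, adjusted p = 0.0881) nor Ccl5 (-0.12, adjusted p = 0.288) passed. Interferon response and antigen presentation had 5 of 24 lower (none adjusted over the list alone; adjusted p = 0.028), among them Isg15 (-0.29), and blood cell markers 3 of 9 lower (3 adjusted over the list alone; adjusted p = 0.0174). With quantile normalization no interferon or blood cell member passed, and 4 tanycyte, 3 region and 1 pituitary marker were lower, with 1 pituitary marker higher. Median centring adds 0.21 to every log2 change of this comparison, which turns the medians of the tanycyte, region, inflammatory and interferon lists positive while their test against the other genes stays downward. In the feeding list, which did not pass (adjusted p = 0.431), 4 of 33 members rose and 5 fell (3 and 3 adjusted over the list alone). With quantile normalization 1 rose and 1 fell. Cpe, a peptide-processing enzyme, rose by 0.32 and Ntrk2, the receptor of brain-derived neurotrophic factor, by 0.27, the latter turning to -0.03 with quantile normalization. Cpe turned to -0.07 with quantile normalization without low-fat replicate 3. Single arrays decided 4 of the 12 list calls: ribosomal proteins did not pass without low-fat replicate 1 (adjusted p = 0.13) or 2 (0.117), interferon genes without low-fat replicate 1 (0.0791) or safflower replicate 5 (0.0838), and astrocyte (0.0602) and blood cell markers (0.172) without low-fat replicate 3.

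With the flaxseed diet, transcripts of cytosolic ribosomal proteins were higher as a list than with the low-fat diet: 69 of 70 members had a positive log2 change, with a median of 0.21 and camera adjusted p = 3.29e-14. The list did not pass with an estimated correlation (adjusted p = 0.951). No member passed over all genes, and 37 passed when adjusted over the list alone. The median was 0.10 after quantile normalization (adjusted p = 0.000397) and lay at percentile 100 of random lists matched on mean signal. The exact permutation of arrays gave p = 0.143 (adjusted p = 0.733): the list's mean relative to all genes was 1.40 ± 0.01 (SD, n = 4) on the flaxseed and 1.23 ± 0.17 (SD, n = 4) on the low-fat arrays, which ranged from 1.075 to 1.453.

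No single gene passed the threshold for flaxseed against low-fat in the limma fit, with 3226 at an unadjusted p under 0.05. The smallest adjusted p was 0.205. The gene of smallest unadjusted p was Taf9b, a subunit of the general transcription machinery, at 9.24 ± 0.06 (SD, n = 4) on low-fat and 9.70 ± 0.16 (SD, n = 4) on flaxseed arrays (log2 change 0.46, SE 0.08). Other log2 changes among the named genes were 0.67 for Bex4, 0.57 for Clxn, 0.40 for Zfp472, -0.44 for Prp2, -0.33 for Chad and -0.27 for Myl2. Npy, the appetite-promoting neuropeptide Y, had a log2 change of 0.42 (SE 0.15) and was above all low-fat arrays in 4 of 4 flaxseed arrays. Hadhb (0.24) and Etfdh (0.21) had positive changes as well. Ordinary least squares without moderation also gave 0 genes, an unadjusted p with a fold of at least 1.5 gave 9, and array weights gave 4713.

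Other lists past the camera test with flaxseed were the respiratory chain (median log2 change 0.11, adjusted p = 0.000255), glutamate and GABA transmission (0.14, adjusted p = 0.00604), antioxidant genes (0.14, adjusted p = 0.0391) and astrocyte markers (0.14, adjusted p = 0.0484) on the positive side, and oligodendrocyte and myelin markers (-0.09, adjusted p = 0.0391), pituitary markers (-0.13, adjusted p = 0.0391) and inflammatory signalling (-0.03, adjusted p = 0.0484) on the negative side. None passed with an estimated correlation (adjusted p = 0.951 for each). The myelin and pituitary medians lay at percentiles 0 and 2.61 of random lists matched on mean signal, the others between 39.0 (inflammatory) and 90.3 (antioxidant). No member of these passed over all genes, and adjusted over the list alone 4 of the glutamate and GABA list, 1 of the antioxidant and 1 of the astrocyte list did. Examples by smallest p were Gabra3 (0.26), Gabra2 (0.34), Ndufs4 (0.19), Ndufa4 (0.34), Prdx1 (0.34), Sod1 (0.22), Il1rn (-0.17) and Nos2 (-0.20). After quantile normalization the glutamate and GABA and the astrocyte medians turned to -0.06 and -0.05 and the inflammatory median to 0.03, and only the ribosomal and myelin lists still passed. Median centring turns the myelin and inflammatory medians positive. Only the ribosomal and respiratory chain lists passed without each single array; the myelin list had an adjusted p of 0.847 without flaxseed replicate 1.

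Between safflower and flaxseed, compared at the same fat content, oligodendrocyte and myelin markers differed as a list. Of 23 tested members, 22 were higher with safflower, with a median log2 change of 0.37 (0.35 after quantile normalization) and camera adjusted p = 1.31e-07. The list did not pass with an estimated correlation (adjusted p = 0.671), and without flaxseed replicate 1 the median was 0.24 with 20 of 23 genes higher (adjusted p = 0.00297). Npy and Agrp, appetite-promoting peptides of the arcuate nucleus, did not pass (adjusted p = 0.246 for both). Npy stood at 9.57 ± 0.33 (SD, n = 5) against 10.16 ± 0.12 (SD, n = 4) with flaxseed (log2 change -0.60, SE 0.14), and Agrp at 6.83 ± 0.15 (SD, n = 5) against 7.27 ± 0.21 (SD, n = 4; log2 change -0.44, SE 0.10). All 5 safflower arrays lay below all flaxseed arrays for both. Ghrh, growth hormone-releasing hormone, had a log2 change of -0.40. None of these genes passed over all genes tested (adjusted p = 0.246).

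The limma fit gave 0 genes past the threshold between the high-fat diets, with 2480 at an unadjusted p under 0.05, 0 by ordinary least squares and 4667 with array weights. Without safflower replicate 4 the count was 90, among them 15 of the 36 named genes: Npy (log2 change -0.69, adjusted p = 0.0466), Ghrh (-0.44), Gabrb2 (0.56), Slc24a2 (0.76), Lss (0.40) and Msmo1 (0.35) passed, and Agrp did not. With all arrays Slc24a2, a sodium-calcium exchanger, had a log2 change of 0.69, Gabrb2 0.48, Lss, the lanosterol synthase of cholesterol synthesis, 0.38, and Msmo1 0.29. The feeding list did not pass (3 of 33 lower adjusted over the list alone; median -0.09, adjusted p = 0.0626), and it passed after quantile normalization (adjusted p = 0.00809) and without flaxseed replicate 3 (0.0107), safflower replicate 2 (0.0225) or safflower replicate 4 (0.0277). It did not pass with an estimated correlation (adjusted p = 0.765) or by exact permutation of arrays (p = 0.143, adjusted p = 0.302).

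The myelin list (4 of 23 higher adjusted over the list alone) also differed between arrays of a diet. The mean of its genes relative to all genes was 0.77 in flaxseed replicate 1 and 1.25 to 1.35 in the other flaxseed arrays. The exact permutation over all arrays gave p = 0.0952 (adjusted p = 0.238). A further 12 lists passed, none of them with an estimated correlation (adjusted p = 0.671 to 0.765). Higher with safflower were glutamate and GABA transmission (median 0.17, adjusted p = 1.23e-06; 9 of 29 adjusted over the list alone), cholesterol synthesis (0.16, adjusted p = 6.12e-06; 2 of 22), endothelial, pericyte and meningeal markers (0.20, adjusted p = 5.28e-05; 7 of 28), fatty acid desaturation (0.12, adjusted p = 0.000568), the respiratory chain (0.07, adjusted p = 0.00552), oligodendrocyte precursors (0.16, adjusted p = 0.0162) and monoamine and opioid signalling (0.09, adjusted p = 0.0214). Lower with safflower were tanycyte and choroid plexus markers (-0.17, adjusted p = 1.23e-06; 10 of 24 adjusted over the list alone), blood cell markers (-0.41, adjusted p = 0.000109; 4 of 9), ribosomal proteins (-0.06, adjusted p = 0.000192), interferon response (-0.10, adjusted p = 0.00171) and pituitary markers (-0.15, adjusted p = 0.00997; 1 of 8). Among random lists matched on mean signal, the respiratory chain median lay at percentile 42.7 and those of the other higher lists between 97.4 and 100, and the medians of the lower lists lay between 0 and 0.54. Lists that did not pass lay as far out, with cortex, hippocampus and amygdala markers at 100, eicosanoid genes at 99.1 and feeding peptides at 0. After quantile normalization the fatty acid desaturation (adjusted p = 0.0844), respiratory chain (0.891), pituitary (0.0814) and monoamine (0.0549) lists did not pass. The respiratory chain list pointed downward with loess scaling, and median centring, which adds 0.11 to every log2 change here, turns the ribosomal and interferon medians positive. Without flaxseed replicate 1 the interferon (adjusted p = 0.0575), precursor (0.107) and respiratory chain (0.107) lists did not pass, nor did the respiratory chain without safflower replicate 5 (0.0578) or the monoamine list without flaxseed replicate 4 (0.095) or safflower replicate 1 (0.0665).

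**Figure D4:**
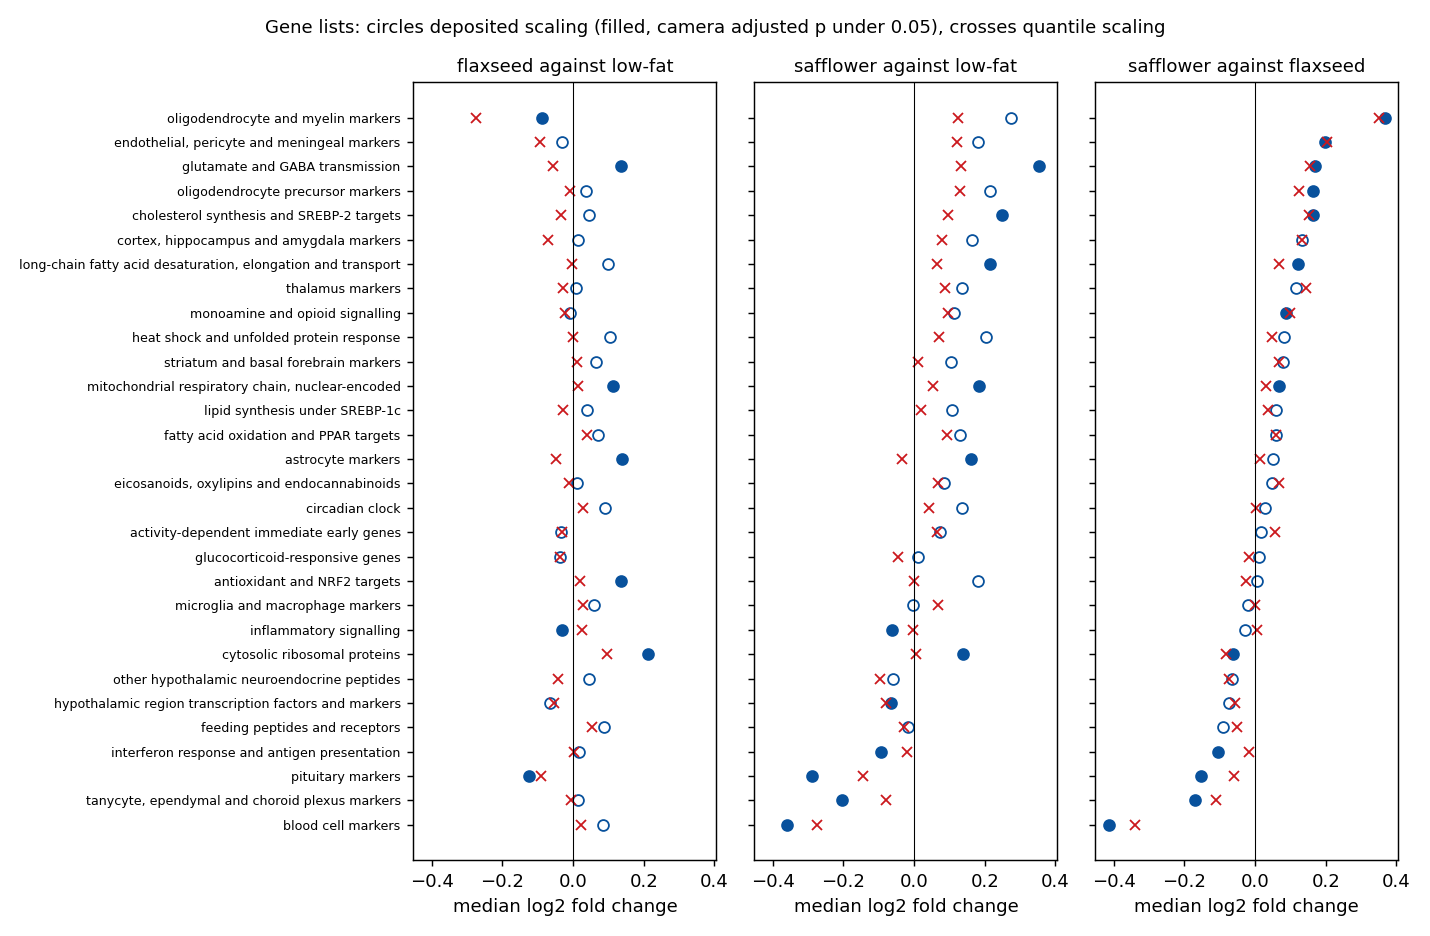
Median log2 fold change (x axis) of each of the 30 gene lists (y axis) in the 3 comparisons; circles give the deposited scaling, filled where the camera adjusted p was under 0.05, and crosses quantile normalization. The myelin list stands at 0.37 for safflower against flaxseed, and the blood cell list at -0.41.

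**Figure D5:**
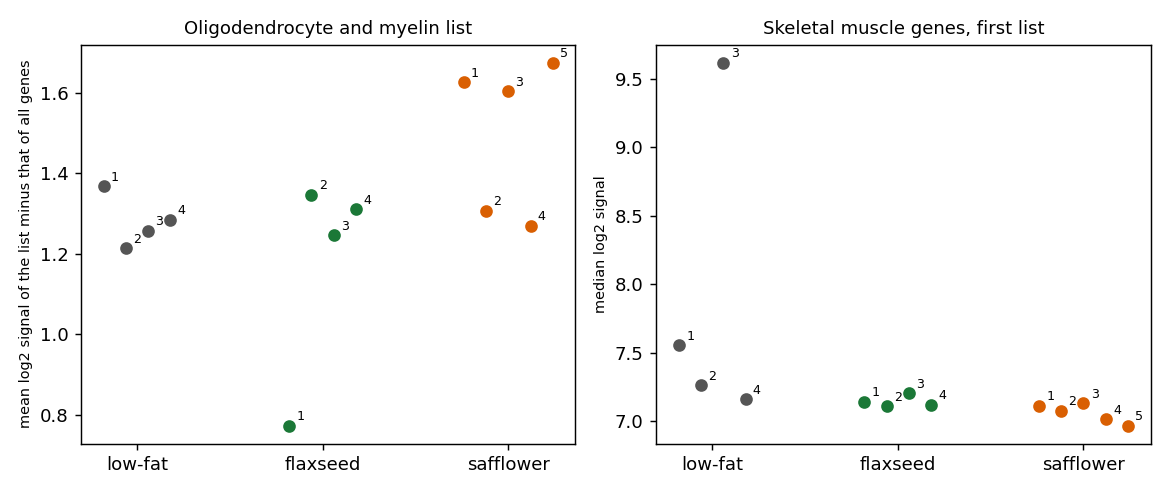
Left, mean log2 signal of the oligodendrocyte and myelin list minus that of all genes (y axis) for each array by diet. Right, median log2 signal of the first list of skeletal muscle genes (y axis), which held genes already seen in these data. The replicate number is beside each point. Flaxseed replicate 1 lies at 0.77 on the left and low-fat replicate 3 at 9.62 on the right.

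For the mean of both high-fat diets against low-fat, 4496 genes passed, 2598 higher and 1898 lower (57.8% higher). As 6377 genes passed for safflower alone and 0 for flaxseed alone, these genes were not shown to be common to both diets. The share higher was 69.3% of 1199 genes after quantile normalization, 41.3% of 1718 after loess and 98.5% of 8222 after median centring, and the count was 0 without low-fat replicate 1, 2025 without low-fat replicate 2 and 2903 without flaxseed replicate 2. The moderated F test found 4062 genes that differed among the 3 diets, 680 after quantile normalization. With replicate number as a block it found 0 (smallest adjusted p = 0.059), although the numbers were not shown to pair the arrays. With the olfactory covariate limma gave 0 genes for the mean of both diets (558 at an unadjusted p under 0.05) and 0 for any difference (556). The count of any difference was 1470 without low-fat replicate 1, 1933 without low-fat replicate 2, and 1552, 2303 and 1628 without safflower replicates 1, 3 and 5. With quantile normalization limma gave 0 genes for any difference without low-fat replicate 1, flaxseed replicate 2 or safflower replicate 1, 2, 3 or 5 (3032 to 3558 at an unadjusted p under 0.05), 1 without low-fat replicate 2 and 325 to 1231 without each other array. For the mean of both diets it gave 0 without low-fat replicate 1 (2966 at an unadjusted p under 0.05) or flaxseed replicate 2 (3749), 1 without low-fat replicate 2 and 155 to 2124 without each other array.

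The changes with either high-fat diet against the shared low-fat arrays were correlated across genes. Pearson's r was 0.79 (Spearman's rho 0.795) and 86.2% of genes had the same sign. The shared arrays alone gave a mean r of 0.538 (0.123 to 0.874) in simulations. With the low-fat arrays split, so that the comparisons shared none, the mean r was 0.506 (0.236 to 0.671), where sharing contributes 0. The simulated share of the same sign was 69.5% on average (50.9 to 87.5). Genes are not independent replicates, and the observed r and share lay within the simulated ranges. The covariance was 0.024, against 0.00538 (0.00126 to 0.0188) in the simulations, a difference of 0.0186. With the low-fat arrays split, and so without sharing, the covariance was 0.0176.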

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

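The tests of signal range, background, muscle and myelin below were chosen after the results were seen, and the counts over other splits of the arrays were planned. The second muscle list was shortened by 2 genes after its array medians had been seen. In 16 of 357 groups of 4 or 5 arrays a single array stood apart from the rest of its diet, where chance gives about 17.8.

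Low-fat replicate 3 stood apart for Agrp (log2 signal 7.093, others 7.235 to 7.257), Irf7 (7.341, others 7.561 to 7.578), Myh4 (8.727, others 6.879 to 7.156), Myl11 (9.287, others 6.858 to 7.187) and Tnnt3 (9.615, others 7.298 to 7.653). Low-fat replicate 1 did so for C19h16orf78 (6.992, others 6.795 to 6.813) and for the median of all transcript clusters (6.743, others 6.675 to 6.684). Flaxseed replicate 1 did so for Bex4 (9.047, others 8.461 to 8.554), Ddx20 (7.623, others 7.448 to 7.467) and Tmem88b (7.927, others 8.523 to 8.619). Flaxseed replicate 3 did so for Ano3 (7.893, others 7.198 to 7.267), Prp2 (7.787, others 7.539 to 7.581), Tnnt3 (7.204, others 7.132 to 7.143), the olfactory receptor median (4.951, others 4.836 to 4.855) and the second muscle list (7.279, others 7.161 to 7.181). Safflower replicate 4 did so for Taf9b (9.775, others 9.489 to 9.563).

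The 6377 genes past the threshold for safflower against low-fat exceeded every other split drawn. Of 100 splits of the 9 arrays, 1, the real one, gave as many, which is the smallest share possible. The highest other gave 1840. Chance is thus an unlikely origin but not excluded, and both a diet effect and a technical difference between the diet groups stay open. Signal range, as far as quantile and loess normalization remove it, is not the whole cause, since 24.1% of the genes passed in the same direction under both. Technical differences that these normalizations leave in place stay open for those genes. For the other 4837 genes signal range stays open. Their median log2 change fell in size from 0.273 to 0.129 with quantile and 0.119 with loess scaling. Their median standard error was 0.0744 (deposited), 0.0741 (quantile) and 0.0608 (loess), so their calls ended mainly with the smaller change. These genes were picked because they did not pass under both other scalings, which favours a smaller change there, so the fall is no evidence on its cause. Lower background on the safflower arrays stays open for the lower dim genes, as olfactory receptor genes had a median log2 change of -0.267 (-0.0863 after quantile normalization), while the negative controls were not clearly lower (exact permutation p = 0.333) and the positive controls were higher (9.29 against 8.99). The spike-in features were lower as well (5.85 against 6.14, exact permutation p = 0.0238, adjusted p = 0.0593). The background features stood at 4.50 against 4.77 (exact permutation p = 0.135, adjusted p = 0.182). With the olfactory median as covariate no gene passed, but that median correlates at -0.94 with the grouping, which raised the median standard error from 0.0775 to 0.179, while the median size of the called changes fell from 0.281 to 0.136 and 54.9% kept their sign, so background stays open for the remaining genes as well, and a diet effect was not tested apart from it.

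Low-fat replicate 3 had high signals of skeletal muscle genes, with a first-list median of 9.62 against 6.97 to 7.56 in the other arrays. The first list held muscle genes already seen in these data, so its median in this array is a description and no test. Muscle RNA in that sample may be the source: a second list of 28 muscle genes lay 0.882 above its median in the other 12 arrays, more than in any other array, and 14 of the genes lay over 1 log2 unit above. Ckm, an abundant muscle transcript, stood at 10.29 in that array and at 8.42 to 8.74 in the other low-fat arrays. On the second list low-fat replicate 1 followed, 0.415 above. The median of that list was 7.32 to 8.06 on the low-fat arrays and 7.07 to 7.28 on all high-fat arrays. The exact permutation p was 0.0286 for flaxseed (adjusted p = 0.0593) and 0.00794 for safflower (adjusted p = 0.0357), each against low-fat. The higher muscle signal was thus not confined to low-fat replicate 3. The 2 lists share no gene, but muscle genes are co-regulated, so a change within the tissue was not tested apart from muscle carried along at dissection.

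Oligodendrocyte and myelin genes were higher as a list with safflower than flaxseed (camera adjusted p = 1.31e-07), with 0 of 23 members past the threshold over all genes. The list did not pass with an estimated correlation (adjusted p = 0.671) or by exact permutation of arrays (p = 0.0952, adjusted p = 0.238). The median lay at percentile 100 of 10000 random lists matched on mean signal. Such lists lack the correlation between these genes, so this percentile decides nothing about signal range as a cause. The list median was 0.37 with the deposited scaling and 0.35 after quantile normalization. Signal range, as far as quantile normalization removes it, thus does not account for the whole of that median. Safflower replicates 2 and 4 had list scores of 1.31 and 1.27, in the range of the other flaxseed arrays, and replicates 1, 3 and 5 had 1.63, 1.60 and 1.67. Thalamus markers parted the same arrays the other way, with 0.67 and 0.73 in replicates 2 and 4 and 0.18, 0.20 and 0.23 in replicates 1, 3 and 5. A larger share of oligodendrocytes or white matter, dissection and diet were not tested apart.

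The other counts over splits were as follows. For the mean of both high-fat diets 1 of 100 groupings of the 13 arrays, the real one with 4496 genes, gave as many (highest other 2190). For any difference among the diets it was 1 of 100 (real 4062, highest other 95). Chance is thus unlikely for both but not excluded, and a technical difference between the diet groups stays open. With replicate number as a block any difference gave 0 genes. For flaxseed against low-fat (35 of 35 splits, highest other 0) and safflower against flaxseed (100 of 100, highest other 1) the real count was 0, which any split reaches, so the splits say nothing about chance there.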

How the results depend on the processing

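Cyclic loess, quantile normalization over the genes tested, quantile normalization with arrays left out, the olfactory covariate and the list permutation were chosen after seeing the data. The cause of a change was not tested except where a smaller or larger set of genes or arrays is part of the setting. Counts follow the order flaxseed against low-fat, safflower against low-fat, safflower against flaxseed, mean of both high-fat diets against low-fat, any difference. Signal over background limits the dim genes: olfactory receptor genes, near background, had a median log2 change of -0.267 with safflower.

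Counts of 0, 6377, 0, 4496 and 4062 became 1, 10003, 0, 7203 and 6511 without a mean filter and 0, 3379, 0, 2213 and 1986 with the filter at the 75th percentile. The 25th percentile filter gave 1 gene for flaxseed. All transcript clusters gave 1, 26502, 0, 16008 and 13611, and an unadjusted p with a fold of at least 1.5 gave 9, 59, 26, 16 and 70. Quantile normalization left 2326, 1199 and 680 for safflower, both diets and any difference, over the tested genes only 3451, 2050 and 1691, cyclic loess 3332, 1718 and 1620, median centring 9620, 8222 and 7996, and quantile normalization without low-fat replicate 3 left 3107, 2124 and 1105. Array weights gave 4713 for flaxseed, 4667 for safflower against flaxseed, 7727 for both diets and 9866 for any difference. The olfactory covariate gave 0 for safflower, both diets and any difference, with larger standard errors. With replicate number as a block, although the numbers were not shown to pair the arrays, any difference gave 0 (smallest adjusted p = 0.059, with 5716 genes at an unadjusted p under 0.05).

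Without single arrays, with the deposited or quantile scaling, flaxseed stayed at 0 to 0, safflower ran from 880 to 6814, safflower against flaxseed from 0 to 90, both diets from 0 to 4910 and any difference from 0 to 4637. With the deposited scaling alone safflower ran from 4512 to 6814. The lists past the test ran from 3 to 9 for flaxseed (8 with all arrays), 10 to 14 for safflower (12) and 13 to 18 between the high-fat diets (13). The correlation of the high-fat effects ran from 0.727 to 0.814 and was 0.506 with the low-fat arrays split.

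Quantile normalization, quantile normalization over the tested genes, cyclic loess, and quantile normalization without low-fat replicate 3 each left 2 lists for flaxseed and 0 for safflower. The estimated correlation and the exact permutation left 0 in all 3 comparisons, fry 0, 2 and 0, and the olfactory covariate 5 for flaxseed. Directions reversed as follows. With quantile normalization Ntrk2 had log2 changes of -0.087 for flaxseed and -0.029 for safflower. With the olfactory covariate the ribosomal list passed downward for safflower (adjusted p = 6.51e-08), Nos2 had 0.034 and Ndufa4 -0.024 for flaxseed, and for safflower Hmgb1 had -0.20, Itgb8 -0.33, Taar6 0.16, Etfdh -0.026 and RT1-Db1 0.13. With quantile normalization without low-fat replicate 3, flaxseed gave Ntrk2 -0.19, Gabra2 -0.16 and Sod1 -0.063, and safflower gave Cpe -0.069, Ntrk2 -0.14 and Sc5d -0.0031.

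The other named genes kept the sign of their log2 change in the settings checked for single genes. Median centring, which raises every safflower against low-fat change, was not among those settings and can turn small negative changes. Of the lists that passed with the deposited scaling, these pointed the other way without passing: with quantile normalization the astrocyte list for both diets, the glutamate and GABA list for flaxseed and the ribosomal list for safflower; with loess the astrocyte list for both diets, the ribosomal list for safflower and the respiratory chain between the high-fat diets; with the olfactory covariate the inflammatory list for both diets, the interferon, region and respiratory chain lists for safflower and the respiratory chain between the high-fat diets; and the myelin list for flaxseed without flaxseed replicate 1. Quantile normalization over the tested genes turned the astrocyte and ribosomal lists for safflower and the respiratory chain between the high-fat diets. Without low-fat replicate 3 it turned the same lists as with all arrays and the antioxidant list for flaxseed. Among lists that had not passed, quantile normalization turned SREBP-1c, heat shock, antioxidant, myelin, eicosanoid, microglia and immediate early genes for safflower and fatty acid desaturation for flaxseed, of those described. Under quantile normalization 24 calls of named genes and 22 calls of lists were lost, under loess 24 and 21. Over all settings that left out 1 array, a call of a named gene was lost 63 times and gained 15 times, and a list call was lost 30 times and gained 8 times.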

Other observations

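Several gene groups did not pass the list test for safflower against low-fat but held members past the threshold. Fatty acid oxidation genes had 6 of 30 members higher (6 adjusted over the list alone, median log2 change 0.13, adjusted p = 0.118), and heat shock and unfolded protein response genes had 11 of 26 higher and 2 lower (12 and 2 adjusted over the list alone, adjusted p = 0.0762). With quantile normalization 3 fatty acid oxidation genes were higher, and heat shock genes had 0 higher and 1 lower. Lipid synthesis under SREBP-1c had 7 of 20 higher and 3 lower (adjusted p = 0.424), antioxidant genes 8 of 23 higher and 1 lower (adjusted p = 0.24), circadian clock genes 5 of 19 higher (adjusted p = 0.24), oligodendrocyte precursor markers 4 of 10 (adjusted p = 0.174), endothelial markers 5 of 28 (adjusted p = 0.197) and oligodendrocyte and myelin markers 3 of 23 (adjusted p = 0.106). With quantile normalization SREBP-1c genes had 1 higher and 1 lower, and antioxidant genes 0 higher and 1 lower. The number higher was then 1 for clock genes, 0 for precursors, 2 for endothelial markers and 0 for myelin markers. Eicosanoid genes had 4 of 34 higher and 6 lower, with a positive median (0.08) and a test that pointed downward (adjusted p = 0.573). Microglia markers had 2 of 22 higher (adjusted p = 0.952), and immediate early genes 1 of 23 higher and 1 lower (adjusted p = 0.886). Quantile normalization gave 2 higher and 1 lower for eicosanoid genes, 3 higher for microglia markers and 0 for immediate early genes.

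Markers of 3 neighbouring brain regions did not pass in any of the 3 comparisons, while the 8 pituitary markers passed in each with the deposited scaling. The pituitary list passed in none with an estimated correlation or after quantile normalization. Its camera adjusted p was then 0.325 for flaxseed and 0.0507 for safflower against low-fat, and 0.0814 between the high-fat diets. For flaxseed it did not pass without low-fat replicate 3 (0.154) or 4 (0.0633) either. Single arrays still stood apart on the mean of a list relative to all genes. The cortex, hippocampus and amygdala list stood at 0.80 in safflower replicate 5 and at 0.02 to 0.18 in the other safflower arrays. The striatum list stood at 0.31 in safflower replicate 1 and 0.27 in flaxseed replicate 3. The thalamus list ran from 0.13 to 0.73. Even dissection was thus not shown. For safflower against low-fat the adjusted p was 0.667 for the thalamus, 0.666 for the striatum and basal forebrain and 0.904 for the cortex, hippocampus and amygdala. Glucocorticoid-responsive genes (adjusted p = 0.38) and neuroendocrine peptides outside the feeding list (adjusted p = 0.404) did not pass either. For flaxseed against low-fat, the adjusted p was 0.582 for feeding peptides, 0.217 for fatty acid desaturation, 0.259 for fatty acid oxidation and 0.217 for eicosanoid genes. Between the high-fat diets it was 0.129 for fatty acid oxidation, 0.573 for eicosanoid genes and 0.0572 for inflammatory signalling.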
